A study of Mus musculus with 6 samples.

How the data were processed

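RNA-seq was made from primary mouse vascular smooth muscle cells in calcifying medium, 3 libraries from wild-type cells and 3 from cells labelled STING knockout. Per the labels' protocols, RNA was extracted with TRIzol, mRNA was taken with oligo(dT) beads and fragmented, and cDNA was primed with random hexamers. Per the submitters' processing notes, fastp, HISAT2 and StringTie and the build GRCm39 were used. The notes give no versions, and the counting rule, the annotation release and the strand setting are not given in the sources used here. The deposited values are whole-number counts per gene, 1 column per library, with no scaling to a common total. Of the 24195 names in the table, 2287 are loci assembled by StringTie (MSTRG names), which took 1.57% ± 0.0471 of the counts in WT and 1.89% ± 0.0111 in the libraries labelled KO (SD, n = 3 each). No column was left unmapped, and the title of each sample gave its group.

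Library totals were 39400215, 44379383 and 37938777 counts for WT 1 to WT 3, and 45889966, 45060494 and 42946965 for KO 1 to KO 3. Genes with low even values outnumbered those with low odd values in every library, 2138 against 1611 in WT 1, so both reads of a pair were probably counted. Counting intervals then come out too narrow, and PCR copies are not independent molecules either, so all intervals on shares cover counting error only. Reads of genes with near-identical copies, overlapping genes and antisense genes cannot be told apart from these counts, and values of gene families such as Lce, Sprr, Tgtp, Slfn and Pcdh are uncertain for single members. No library pair held the same values, and all 6 libraries were kept as replicates. Within groups, counts differed by a chi-square of 3.10 to 18.5 per degree of freedom. The lowest value was that of KO 2 against KO 3. KO 1 differed from KO 2 by 15.6 and from KO 3 by 14.3, and the WT pairs differed by 7.55 to 18.5. KO 2 and KO 3 may therefore be less independent than the other libraries, which the labels do not settle. Log2 CPM correlated at 0.989 to 0.995 within groups and at 0.952 to 0.960 between them, over genes, which are not independent replicates.

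Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 15995. Of the rest, 1760 had 0 counts in every library. Counts were scaled by TMM, whose factors averaged 0.902 in WT and 1.11 in the libraries labelled KO, and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) under R 4.3.3, with the group as the only term and 4 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Folds, SEs and intervals come from this model, and means ± SD are of TMM-scaled CPM. For genes with under 20 counts over the WT libraries, counts are given in place of folds, except the log2 value of Nlrp3. The 32 gene lists were fixed before the data were examined and tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, then with an estimated correlation, and with fry. The list adjusted p is Benjamini-Hochberg over the 32 lists. No list was called with an estimated correlation. For the contractile list and the epithelial and mesothelial list the estimate, 0.00313 and −0.0192, lay below the preset. In these lists the loss of the call is therefore not due to a higher correlation among members. With an estimated correlation camera uses the 4 residual degrees of freedom, and with the preset far more, drawn from the number of genes. Few lists could thus be called with an estimated correlation, and a call lost there does not show that a list was unchanged.

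Genes are named by a rule also fixed before the data were examined. It took Sting1, Stat1, Nlrp3, Runx2, Bmp2, Msx2, Sox9, Alpl, Spp1, Acta2, Myh11, Tagln, Cnn1, Il1b and Casp1 whatever their test gave. It added the 12 largest rises and 12 largest falls among called genes whose groups did not overlap and whose higher group mean was at least 5 CPM, leaving out predicted genes and immunoglobulin segments. It further took up to 4 members of each described list with the smallest p, and up to 6 called genes within 10 Mb of Sting1 with the smallest p. Positions came from RefSeq genes of GRCm38.p6, a build other than that of the deposited counts, so they served only to find neighbours and no coordinates are given. Of the genes tested, 91.6% had a position by symbol.

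On counts simulated for this comparison (15613 genes tested, 200 changed), edgeR recovered 67.2% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 92.4% of those changed 4-fold, with 16 false calls. The simulated changes were few and balanced in direction. In the data 10157 of 15995 genes were called, and changes of at least 1 on the log2 scale were 2329 higher and 803 lower. The simulated rates therefore need not hold for the data. Camera called 0 of 32 lists when none was changed and called the 1 list that was raised. Genes were drawn independently in this simulation. In the data the estimated correlation was 0.580 for type I interferon and 0.503 for cell cycle genes. False list calls under such correlation were therefore not assessed. The alternatives were a replicate block, no filter, a mean of at least 50 counts, DESeq2 size factors, quantile normalization, the DESeq2 1.42.0 Wald test, limma-voom, limma-trend with array weights, a change of at least 1 on the log2 scale and leaving out each library. Scaling by library totals and leaving out assembled loci were added after seeing the data, as were 2 alternatives of the neighbourhood test. Pseudocounts and a fit without a trend had been foreseen for normalized values only and did not apply to counts. Checks used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.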

Results

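Poly(A)-selected RNA was sequenced from primary vascular smooth muscle cells of mice, the contractile cells of the vessel wall, after culture in calcifying medium. One group of 3 libraries came from wild-type cells (WT 1 to WT 3) and the other 3 came from cells labelled STING knockout (KO 1 to KO 3). STING, encoded by Sting1, is the adaptor that passes on the signal of cytosolic DNA sensing. The deposited table gave whole-number counts for 24195 genes or assembled loci. Library totals ran from 37938777 counts in WT 3 to 45889966 in KO 1. The design implies a single comparison, libraries labelled KO against WT, and the study's stated question was which genes lie downstream of STING. The labels do not say whether the libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical.

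Sting1 RNA was present in every library. The counts of Sting1 were 1378, 1530 and 1385 in WT 1 to WT 3, and 1674, 1652 and 1665 in KO 1 to KO 3. After TMM scaling Sting1 stood at 39.2 ± 0.770 CPM (CPM, counts relative to the scaled library total; SD, n = 3) in WT and 33.7 ± 1.24 CPM (SD, n = 3) in the libraries labelled KO, which is 85.9% of the WT level with a 95% interval of 77.7% to 95.02%. The log2 difference was −0.22 ± 0.05 (SE) with an edgeR adjusted p of 0.00445, and a 2-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. With scaling by library totals alone, the log2 difference of Sting1 was 0.08 (edgeR adjusted p = 0.20), so its direction depended on the scaling. The knockout allele is not described in the labels, and counts per gene do not show which exons the reads came from. The group is therefore called "labelled KO" throughout, and each direction below is a difference between labelled libraries.

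**Figure D1:**
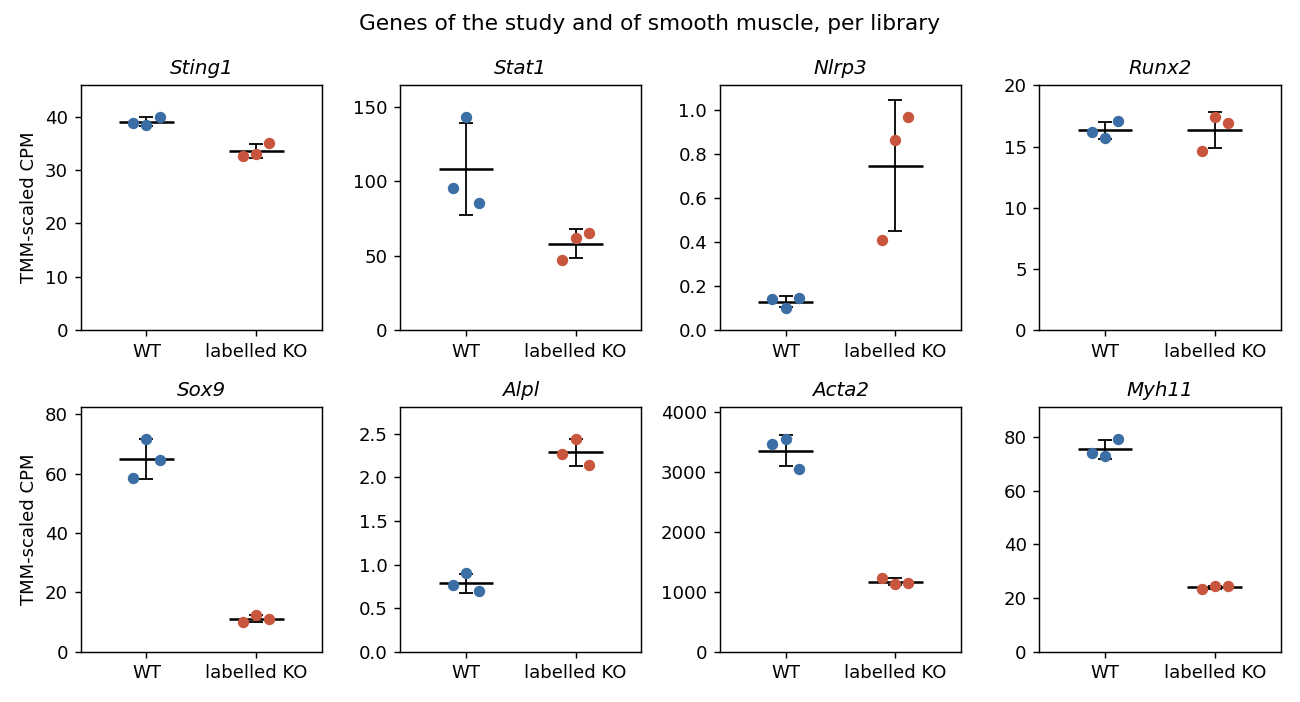
TMM-scaled CPM (linear axes from 0) of 8 genes in the 3 WT libraries (blue) and the 3 libraries labelled KO (red); points are libraries, bars the mean ± SD. Sting1 lies at 33.7 CPM in the libraries labelled KO against 39.2 CPM in WT. Sting1, Stat1, Sox9, Acta2 and Myh11 lie lower and Alpl and Nlrp3 higher in every library labelled KO than in every WT library, and Runx2 overlaps.

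The 12 largest rises in the libraries labelled KO, by the rule given with the processing, were led by Cxcl13 and the 12 largest falls by Eln. Cxcl13, a B-cell chemoattractant, had 4 counts over the 3 WT libraries and 3956 over the 3 labelled KO. Nos2, the inducible nitric oxide synthase, had 8 and 938 counts, Ppbp, a CXC chemokine, 8 and 1261, Xirp2 17 and 1494, Atg9b 13 and 743, and Lrrn4 17 and 771. Serpinb2, an inhibitor of plasminogen activators, rose from 8.69 ± 2.15 to 415 ± 70.1 CPM (SD, n = 3 each), or 47.5-fold. Cxcl2 rose 38.8-fold, Bcl2l15 36.3-fold, Calca, which encodes calcitonin and its gene-related peptide, 29.3-fold, and the cornified envelope genes Lce1h and Lce1g 42.0-fold and 32.6-fold.

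Eln, which encodes elastin, fell from 86.4 ± 30.1 to 1.03 ± 0.115 CPM (SD, n = 3 each), 83.5-fold. Elobl was 38.7-fold lower, A2m, a protease inhibitor, 26.6-fold, Igfbp4, which binds insulin-like growth factors, 13.2-fold, and Comp, a cartilage matrix protein, 12.6-fold. Cyp26b1, which degrades retinoic acid, fell from 732 ± 50.6 to 61.1 ± 6.70 CPM (SD, n = 3 each). Col28a1, Stc1, Adamtsl3, Bmx and Oxtr, the oxytocin receptor, were between 11.4-fold and 12.3-fold lower. Col2a1, the main collagen of cartilage, fell by 4.84 on the log2 scale. Without WT 1, which held 1369 of its 2214 WT counts, Col2a1 fell by 4.01 on that scale.

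With edgeR's quasi-likelihood test, 10157 of the 15995 genes tested passed a Benjamini-Hochberg adjusted p of 0.05, 5233 of them higher and 4924 lower in the libraries labelled KO. A change of at least 1 on the log2 scale was met by 3132 of them, 2329 higher and 803 lower. Many of these rises were of weakly expressed genes. Of the 1980 with a known transcript length, 837 lay under 1 CPM in the libraries labelled KO. Scaling by library totals, chosen after seeing the data, raised the median log2 difference of all genes tested from 0.03 to 0.33 and gave 9189 higher and 2335 lower genes, so small changes are relative to the TMM baseline. The libraries labelled KO also had more genes with at least 1 count, 20481 ± 90.1 against 17474 ± 112 (SD, n = 3 each), and 79.8% of the 957 genes seen in all 3 of them and in no WT library had a mean below 10 counts.

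**Figure D2:**
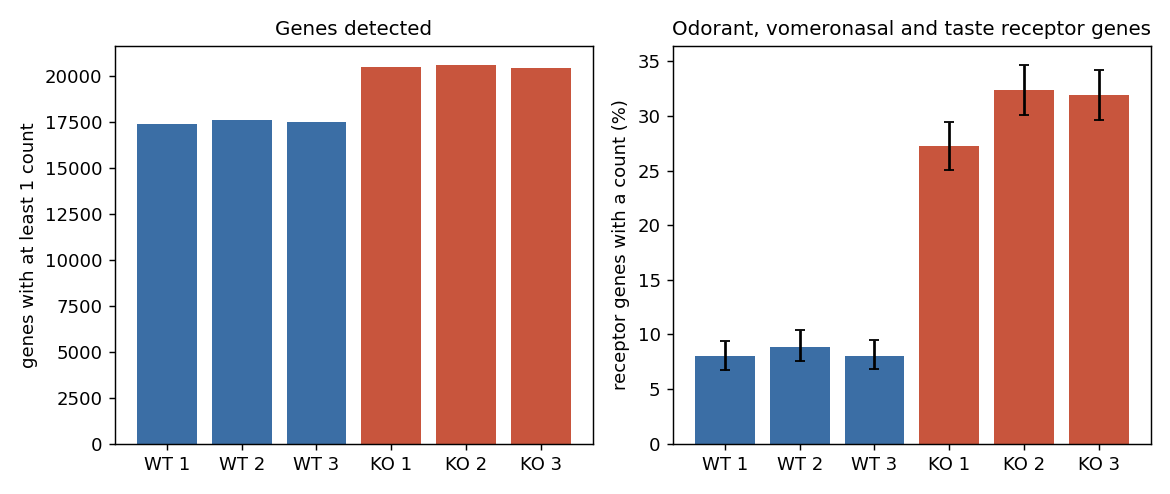
Left, number of genes with at least 1 count in each library (bars from 0); right, percent of 1586 odorant, vomeronasal and taste receptor genes with at least 1 count, with Wilson 95% intervals as error bars. WT libraries are blue and those labelled KO red; the libraries labelled KO hold 20402 to 20579 genes with counts and WT 17373 to 17595, and receptor genes are seen at 27.2% to 32.3% against 8.01% to 8.89%.

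The study's title names STAT1 and NLRP3. Stat1, the transcription factor that carries interferon signals, fell 1.87-fold, from 108 ± 30.9 to 58.1 ± 9.74 CPM (SD, n = 3 each; log2 −0.90 ± 0.18 SE, edgeR adjusted p = 0.00159). These are mRNA levels, and phosphorylation of STAT1 is not measured here. Nlrp3, the sensor of the inflammasome, was low in every library and rose in those labelled KO, from 14 to 110 counts over 3 libraries each (log2 2.52 ± 0.46 SE, edgeR adjusted p = 0.000847). Casp1, the inflammasome protease, rose 1.56-fold to 16.9 ± 2.05 CPM (SD, n = 3; edgeR adjusted p = 0.000242). Nlrp3 reached only 0.748 ± 0.296 CPM (SD, n = 3) in the libraries labelled KO. Macrophage and leukocyte markers rose in 12 of 24 cases and fell in 3 in the same libraries. The counts therefore do not show in which cells Nlrp3 and Casp1 rose. Il1b had 3, 0 and 0 counts in WT and 0, 7 and 0 in the libraries labelled KO and was too low to test.

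Type I interferon response genes mostly fell or did not pass. Of 54 tested members, 24 fell (23 adjusted over the list alone), 2 rose and 28 did not pass. Slfn5 fell 2.25-fold, Ifi47, an interferon-inducible GTPase, 2.08-fold and Isg20, an antiviral exonuclease, 1.56-fold, whereas Slfn2 rose 1.75-fold. The list was called lower by camera (adjusted p = 0.0230), but not with an estimated correlation (adjusted p = 0.814), and not without WT 2 (7 higher, 19 lower; adjusted p = 0.161) or without KO 1 (3 higher, 15 lower; adjusted p = 0.113). Total-count scaling gave 6 higher and 13 lower members. Interferon gamma and STAT1 targets went both ways, with 12 of 32 higher and 11 lower (the same numbers adjusted over the list alone; camera adjusted p = 0.696), 7 and 9 after quantile normalization, and 17 and 7 with total-count scaling. Upp1, uridine phosphorylase, rose 5.16-fold, and the near-identical GTPase genes Tgtp1 and Tgtp2 were 2.97-fold and 3.18-fold lower, with reads that cannot be assigned firmly to either copy.

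Within the inflammasome and pyroptosis list 10 of 20 tested members rose and 4 fell, also adjusted over the list alone, and camera did not call it (adjusted p = 0.172). P2rx7, the ATP-gated channel upstream of NLRP3, rose 2.07-fold and Casp4, the sensor of intracellular lipopolysaccharide, 1.47-fold, while Nek7, a partner of NLRP3, fell 1.78-fold and Txnip 1.62-fold. As with Nlrp3, the counts do not show in which cells these genes changed. In the cGAS-STING pathway list 12 of 24 members fell (13 adjusted over the list alone) and 5 rose (camera adjusted p = 0.200). DESeq2 size factors gave the same numbers, 5 higher and 12 lower, whereas quantile normalization gave 8 higher and 7 lower and total-count scaling 10 higher and 4 lower. Leaving out WT 1 or KO 1 gave 3 higher and 10 lower, and leaving out WT 3 gave 3 higher and 13 lower. Samhd1, a dNTP hydrolase, fell from 447 ± 4.91 to 150 ± 7.54 CPM (SD, n = 3 each), and Ikbke, a kinase related to TBK1, rose 3.15-fold. Stim1 and Zdhhc3 fell 1.57-fold and 1.53-fold.

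Of 29 tested contractile smooth muscle genes, 21 fell, 2 rose and 6 did not pass, with the same numbers adjusted over the list alone. Acta2, smooth muscle actin, fell from 3364 ± 266 to 1173 ± 58.3 CPM (SD, n = 3 each). Myh11, smooth muscle myosin, fell 3.15-fold, Cnn1, calponin, 2.55-fold, Tagln, transgelin, 1.96-fold, Lmod1, leiomodin, 2.77-fold, Sorbs1 3.14-fold and Itga8, an integrin subunit, 10.8-fold. Camera called the list lower (adjusted p = 2.56e-05), and did not call it in the setting with an estimated correlation (adjusted p = 0.239). That estimate, 0.00313, lay below the preset 0.01, so a higher correlation among members did not end the call. In the same libraries 18 of 20 endothelial markers rose, and so did 9 of 10 tested epithelial and mesothelial markers, from a list of 16.

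Genes of bone and cartilage formation did not move one way. Runx2, the master regulator of osteoblasts, stood at 16.3 ± 0.700 CPM in WT and 16.3 ± 1.47 CPM in the libraries labelled KO (SD, n = 3 each; edgeR adjusted p = 0.993), although library totals alone as scaling gave Runx2 a log2 difference of 0.30 (edgeR adjusted p = 0.00767). Msx2 stood at 1.91 ± 0.279 and 1.99 ± 0.341 CPM (SD, n = 3 each; edgeR adjusted p = 0.810). Alpl, the alkaline phosphatase of mineralizing cells, rose 2.89-fold but only to 2.29 ± 0.150 CPM (SD, n = 3), Bmp2 rose 2.88-fold to 2.83 ± 0.604 CPM (SD, n = 3), and Spp1, osteopontin, rose 1.20-fold. The chondrogenic factor Sox9 fell 5.81-fold, from 65.0 ± 6.64 to 11.2 ± 1.07 CPM (SD, n = 3 each), Bmp4 6.32-fold and Ogn, a small leucine-rich proteoglycan, 6.96-fold. Over the osteochondrogenic list 7 of 32 members rose, 10 fell and 15 did not pass, also adjusted over the list alone (camera adjusted p = 0.200). Quantile normalization and total-count scaling led camera to call the list lower (adjusted p = 0.0368 and 0.0133). With total-count scaling 12 members were higher and 9 lower. The median log2 change of the list, 0.26, then lay below the 0.33 of all genes tested, and camera compares a list with the other genes.

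Among calcification inhibitors and genes of pyrophosphate handling, 11 of 18 fell and 4 rose, also adjusted over the list alone. Gas6, a ligand of the AXL receptor, fell from 2084 ± 323 to 376 ± 16.0 CPM (SD, n = 3 each), Smad6, an inhibitor of BMP signalling, 3.08-fold and Grem1, a BMP antagonist, 3.11-fold. Camera gave an adjusted p of 0.0483, and 0.506 with an estimated correlation. Leaving out WT 1 raised the adjusted p to 0.0660, leaving out WT 3 to 0.0953 and leaving out KO 1 to 0.0988. The call was also lost without a filter, with a mean of at least 50 counts, after quantile normalization and without assembled loci (adjusted p = 0.0550 to 0.0741). Total-count scaling gave 6 higher and 8 lower, with the call kept (adjusted p = 0.00231).

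Collagens and matrix genes fell in 26 of 33 cases (27 adjusted over the list alone), with 5 higher. Col14a1 fell 8.80-fold, Fbln5, which assembles elastic fibres, 3.29-fold, Fbn1, fibrillin, 2.92-fold and Col4a2, of basement membranes, 2.67-fold. The camera adjusted p was 5.10e-06, and the adjusted p with an estimated correlation 0.454. TGF-beta and BMP targets fell in 16 of 25 cases and rose in 6, also adjusted over the list alone (camera adjusted p = 0.0107; adjusted p = 0.454 with an estimated correlation). The ligands Tgfb2 and Tgfb3 fell 2.95-fold and 3.27-fold and Ltbp1, which holds latent TGF-beta in the matrix, 2.93-fold, while Grem2, a BMP antagonist, rose 3.22-fold. After quantile normalization the TGF-beta and BMP list was not called (adjusted p = 0.116), and with total-count scaling it was (adjusted p = 0.000496), with 10 members higher and 13 lower. Endothelial markers rose and fibroblast markers fell in the same libraries.

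NF-kB cytokines and chemokines rose in 30 of 37 cases and fell in 4, also adjusted over the list alone. The neutrophil chemoattractants Cxcl1 and Cxcl5 rose from 8.80 ± 1.61 to 221 ± 3.10 CPM and from 50.3 ± 6.30 to 629 ± 4.36 CPM (SD, n = 3 each), and Lif, a cytokine of the interleukin-6 family, rose 10.7-fold. Camera called the list higher (adjusted p = 3.49e-07; adjusted p = 0.255 with an estimated correlation). Targets of p53 and genes of senescence rose in 20 of 28 cases (21 adjusted over the list alone) and fell in 4. Plk2 rose 4.35-fold, Pmaip1, a pro-apoptotic BH3 protein, 4.54-fold, Btg2, an antiproliferative gene, 2.74-fold and Trp53inp1 2.43-fold. For this list the camera adjusted p was 0.000959, and 0.454 was the adjusted p with an estimated correlation. Macrophage and leukocyte markers rose in 12 of 24 cases and fell in 3 in the same libraries, with 7 higher and 4 lower after quantile normalization.

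Cell cycle genes mostly fell. Of 40 tested, 36 fell (37 adjusted over the list alone) and 1 rose. Mki67, the proliferation marker, fell 2.32-fold, Top2a, the topoisomerase of dividing cells, 2.11-fold, and the spindle genes Kif20a and Nusap1 2.38-fold and 2.37-fold. The camera adjusted p was 2.90e-09, and the adjusted p with an estimated correlation 0.454. Genes of cholesterol synthesis fell in 20 of 24 cases (21 adjusted over the list alone) and none of the 24 rose. Sqle, squalene epoxidase, fell 2.29-fold, Lss, lanosterol synthase, 2.11-fold, Nsdhl 2.09-fold and Cyp51 1.95-fold. The camera adjusted p was 1.75e-07, and the adjusted p with an estimated correlation 0.450. As for the other groups, endothelial markers were higher in these libraries.

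Markers of other cell types moved apart. Of 20 endothelial markers 18 rose, with Plvap at 38.5 ± 1.75 CPM against 6.97 ± 1.11 CPM in WT (SD, n = 3 each), Robo4 6.29-fold, Mmrn2 4.15-fold and Tek, the angiopoietin receptor, 3.64-fold higher. The exceptions, named after their values were seen, were Eng, endoglin, which fell from 377 ± 11.6 to 259 ± 12.2 CPM (SD, n = 3 each), and Flt1, at 53.8 and 54.6 CPM (edgeR adjusted p = 0.826). Epithelial and mesothelial markers rose in 9 of 10 tested cases, with Msln, mesothelin, 3.45-fold and Krt19, keratin 19, 2.56-fold higher, and Cldn4, a tight-junction claudin, going from 5 to 304 counts over 3 libraries each. This list holds 16 genes. The filter lets a gene pass through the libraries labelled KO alone, which favours rises among genes with few WT counts. Without a filter 11 of the 16 rose and 0 fell. Fibroblast markers fell in 15 of 19 cases and 1 rose, with Ly6c1 6.14-fold, Pdgfra 2.68-fold and Gsn, gelsolin, 2.01-fold lower. The camera adjusted p was 6.14e-05 for endothelial, 0.000496 for epithelial and mesothelial and 0.000209 for fibroblast markers, and the adjusted p with an estimated correlation 0.454, 0.255 and 0.454. These 3 lists gave the same numbers adjusted over the list alone.

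**Figure D3:**
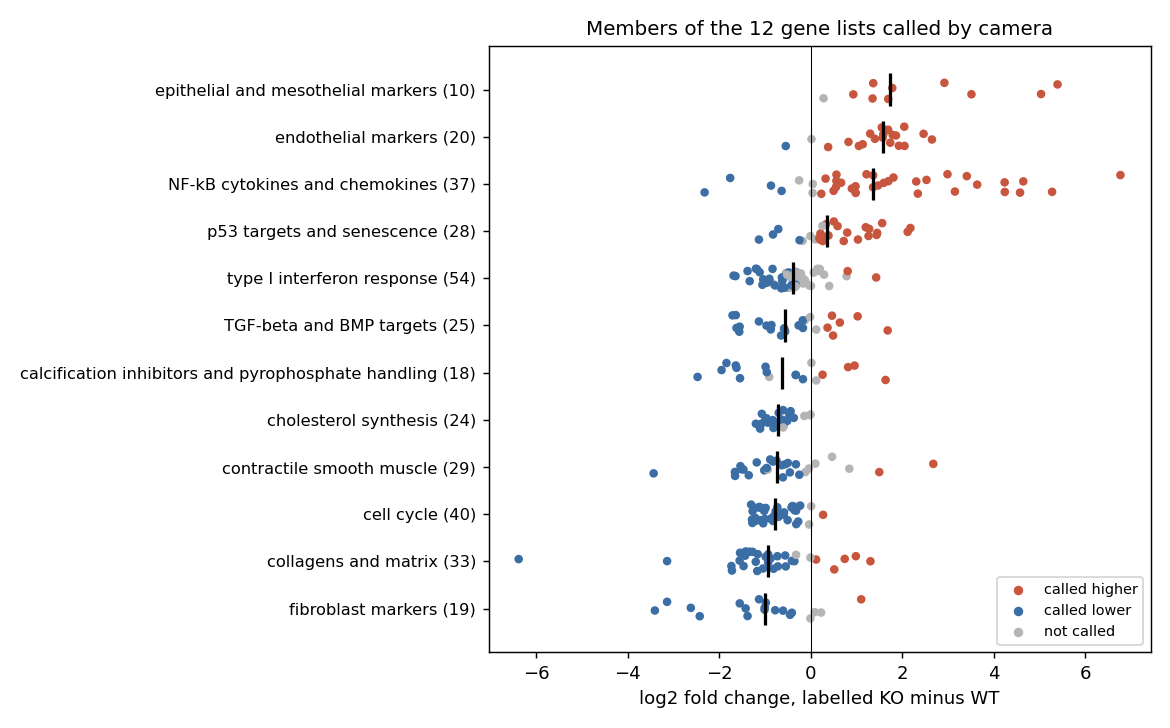
Log2 fold change (labelled KO minus WT, horizontal axis) of each tested member of the 12 gene lists that camera called, with the number tested in brackets; red and blue points passed the test in edgeR as higher or lower in the libraries labelled KO, grey points did not pass, and black bars are medians. Endothelial, epithelial and NF-kB lists lie mostly to the right of 0, and the cell cycle, cholesterol, matrix, contractile and fibroblast lists mostly to the left.

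The remaining lists were not called by camera. Macrophage and leukocyte markers (adjusted p = 0.0805) included Cd68, 4.35-fold higher, and Adgre1, which encodes F4/80, 2.29-fold higher. Nerve and glia markers rose in 9 of 14 cases and fell in 3 (adjusted p = 0.0805), with Plp1 2.49-fold higher and Tubb3 2.55-fold lower. Genes of the NRF2 oxidative stress response rose in 21 of 31 cases and fell in 10 (adjusted p = 0.0600), with Txnrd1, thioredoxin reductase, 2.87-fold and Srxn1, sulfiredoxin, 2.62-fold higher. Genes of modulated (synthetic) smooth muscle split into 10 higher and 12 lower of 24 (adjusted p = 0.606), among them Mmp13, a collagenase, 21.3-fold higher and Col8a1 5.52-fold lower. JAK-STAT components split into 10 higher and 14 lower of 30 (adjusted p = 0.378), with Cish, a cytokine-induced inhibitor, 3.85-fold higher and Il6st, the shared interleukin-6 receptor subunit, 2.54-fold lower. Complement genes split into 5 higher and 9 lower of 19 (adjusted p = 0.328), with Cfh, complement factor H, 4.77-fold lower and Cd55 2.83-fold higher. With total-count scaling the larger side turned for modulated smooth muscle (12 higher, 8 lower), JAK-STAT (17 higher, 11 lower) and complement genes (7 higher, 6 lower), and with quantile normalization for modulated smooth muscle (10 higher, 8 lower). Camera called the leukocyte list without WT 3 or KO 2 (adjusted p = 0.0481 and 0.0404) and the NRF2 list without KO 2 or KO 3 (adjusted p = 0.0436 and 0.0274). The TMM counts of these 6 lists were the same adjusted over the list alone.

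Glycolysis and hypoxia genes were higher in 7 and lower in 16 of 27 cases (camera adjusted p = 0.107), with Adm, adrenomedullin, 3.67-fold lower. Antigen presentation by MHC class I had 9 higher and 3 lower of 21 (adjusted p = 0.361), with Tap1, a peptide transporter, 1.71-fold higher. The unfolded protein response had 6 higher and 11 lower of 26 (adjusted p = 0.388), autophagy and lysosome 7 and 11 of 29 (adjusted p = 0.410), Hox genes 9 and 10 of 27 (adjusted p = 0.795), adipocyte markers 5 and 4 of 13 (adjusted p = 0.706), and skeletal and cardiac muscle markers 4 and 1 of 11 (adjusted p = 0.606). Oxidative phosphorylation had 9 higher and 4 lower of 30 (6 and 3 adjusted over the list alone; adjusted p = 0.606), and cytosolic ribosomal proteins 14 and 1 of 49 (4 and 0 adjusted over the list alone; adjusted p = 0.107, and 0.0264 without KO 2 and 0.0455 without KO 3). The larger side of several of these lists depended on the scaling. Quantile normalization gave 14 higher and 7 lower glycolysis, 14 and 5 unfolded protein, 16 and 5 autophagy, 2 and 3 adipocyte and 2 and 5 skeletal and cardiac muscle genes. Total-count scaling gave 13 higher and 7 lower glycolysis, 17 and 5 unfolded protein, 17 and 3 autophagy, 14 and 6 Hox and 16 and 1 MHC class I genes. Ribosomal genes were higher in 47 of 49 cases with either scaling, and oxidative phosphorylation genes in 19 with quantile normalization and 27 with total-count scaling. Higher ribosomal genes numbered 7 without WT 1, 4 without WT 3 and 6 without KO 1. Oxidative phosphorylation had 4 higher and 3 lower without WT 1 or WT 3, and 6 higher and 7 lower without KO 1. MHC class I genes had 6 higher and 5 lower of 22 without WT 1.

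The 4 tested sex-linked genes, all on the Y chromosome, were detected in every library and were called lower (adjusted p = 0.0805 as a list), with Ddx3y 1.27-fold lower, and total-count scaling ended the calls of all 4. Ddx3y also lost its call after quantile normalization, tested with limma (adjusted p = 0.0665). In edgeR Kdm5d lost its call with a mean of at least 50 counts (adjusted p = 0.0745) and without KO 2 (0.0557), and Uty with a mean of at least 50 counts (0.0691), without KO 1 (0.0634) and without KO 2 (0.0644). Except where given, the TMM counts of this and the lists from glycolysis on were the same adjusted over the list alone.

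Genes near Sting1 on chromosome 18 were called less often than other genes. Within 10 Mb of Sting1, 78 of 155 tested genes were called (50.3%), against 9401 of 14501 elsewhere (64.8%), an odds ratio of 0.550 with a 95% interval of 0.395 to 0.765 (2-sided Fisher's exact test, p = 0.000257). The called genes with the smallest p in this window were Arap3, Hbegf, a ligand of the EGF receptor, Egr1, an immediate-early transcription factor, and Reep2, with log2 rises of 2.04, 1.71, 1.86 and 1.86, and Kif20a and Lims2, with falls of −1.25 and −0.72. The window holds 45 tested protocadherin genes, whose shared exons make single counts uncertain, and 15 of them were called. Without protocadherin genes the odds ratio was 0.728 (2-sided Fisher's exact test, p = 0.109), so the lower share was no longer called.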

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

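Most tests in this part were chosen after the results were seen. Written beforehand were only the thinning of libraries, the subtraction of background and the second endothelial list.

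A signal outside the genes compared stood out. Of the 1586 odorant, vomeronasal and taste receptor genes in the table, of which 31 were tested, 30.5% ± 2.83 had a count in the libraries labelled KO and 8.32% ± 0.492 in WT (SD, n = 3 each). The Wilson 95% intervals were 25.1% to 29.5% in KO 1, the lowest of its group, and 7.59% to 10.4% in WT 2, the highest of its group.

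The wider set of genes with counts in the libraries labelled KO was weighed against depth and background. Depth is argued against, since thinning every library to 37938777 counts left a gap of 2961 genes out of 3007. Background reads spread over genes remain a candidate explanation of the extra detected genes, since after thinning receptor genes had a count 3.584 times as often in the libraries labelled KO. Of the rises of at least 1 on the log2 scale, background at the rate of the receptor genes does not account for most. The 95th percentile of receptor gene counts per kb, 2.24 to 2.32 in KO 1 to KO 3, was subtracted. After that, 91.41% of the 1980 with a known length (85.02% of 2329) still rose by as much. Of those under 1 CPM in the libraries labelled KO, 85.3% did. The filter had kept only 31 of the 1586 receptor genes, so most genes at that level were probably removed beforehand. This outcome was thus likely from the start, and smaller rises were not tested. Whether the background came from genomic DNA, unspliced RNA or the cells themselves stays open, and so does an effect of genotype, which was not tested separately.

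Sting1 RNA in the libraries labelled KO was weighed against exchanged libraries and against the kind of allele. An exchange between the groups would not account for it with an allele that removes the transcript. The lowest library held 81.81% of the Sting1 CPM of the highest, and no regrouping gives a group that lacks the transcript. With an allele that keeps the transcript, Sting1 levels cannot show an exchange, which therefore stays open. An allele that leaves most of the transcript may account for it, but counts per gene do not show the changed exons, and the level of 85.94% of WT leaves this open. Cells of another genotype in place of the knockout stay open for the same reason.

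The rise of endothelial markers was weighed against more endothelial cells, fewer smooth muscle cells and background. A second list of endothelial genes, fixed before its values were examined, moved likewise: 18 of 20 tested rose and 1 fell (Clec14a). The median log2 change was 1.575 with a bootstrap 95% interval of 1.23 to 1.69, against 1.58 for the first list. That interval resampled genes, which are not independent replicates, so it does not measure the spread between libraries. A larger share of endothelial cells may account for the rise, although Eng fell and Flt1 did not pass. Also, 19 of the 20 genes of the first list and 15 of the second already stood at 1 CPM or more in WT. The most abundant of those that rose were Cdh5 at 92.6, Pecam1 at 75.7 and Emcn at 68.5 CPM in the first list and Cd93 at 79.0 CPM in the second, in the libraries labelled KO. A lower share of smooth muscle alone stays open. The endothelial and fibroblast medians lay 2.588 apart, but smooth muscle cells may themselves express the fibroblast genes. Gsn and Col14a1, the latter also in the matrix list, stood at 1308 and 825 CPM in WT. Epithelial, nerve and leukocyte lists also had raised medians (log2 1.74, 1.01 and 0.33), while 21 of 29 contractile genes fell. Camera called neither the nerve nor the leukocyte list in the main setting. With a mean of at least 50 counts it called the nerve list higher (camera adjusted p = 0.0363). Background is argued against, since the median called marker of the first list had 862 counts in the libraries labelled KO. That is 215.6 times the 95th percentile of receptor genes (4.0, both as means over the 3 libraries). An effect of genotype on these genes within one cell type stays open.

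As to chance, the real grouping gave 10157 genes and the highest of the other groupings 0, and 1 of the 10 splits of the 6 libraries gave as many, but 10 splits are too few for a share under 0.05. Every other grouping mixed both labels on both sides, which moves the group difference into the residual spread. A count of 0 was thus likely there from the start, and no conclusion on chance is drawn.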

How the results depend on the processing

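Total-count scaling, the leaving out of assembled loci and the last 2 neighbourhood tests were chosen after seeing the data. The count of called genes ran from 8698, with a mean of at least 50 counts, to 10693, with array weights, over the planned settings that keep the threshold, and from 9217 to 10007 when a library was left out. Quantile normalization called 9758, of which 7695 were shared in the same direction and 85 went the opposite way. Requiring a change of at least 1 on the log2 scale gave 3132 (2329 higher, 803 lower), by the construction of that setting. Total-count scaling gave 11524, of which 9189 were higher and 2335 lower, because it moves the median of all genes to 0.33. It also turned Sting1 to 0.0795, Ndufs1 to 0.1147, Kdm5d to 0.1155 and Uty to 0.0937. Runx2, which was not called, turned to −0.0016 with the replicate block, −0.0122 without a filter, −0.0037 after quantile normalization and −0.0022 with limma-voom, and Msx2, likewise not called, to −0.3842 after quantile normalization. Leaving out a library gave Runx2 −0.0514 to 0.0701 and Msx2 −0.0439 to 0.1903. The number of lists called went from 12 to 0 with an estimated correlation, where camera uses only 4 degrees of freedom. It went to 21 with fry for direction and 31 with fry for either direction, tests that do not compare a list with other genes. The other settings called 10 to 15. The calcification inhibitor list lost its call in the 7 settings given with it, 3 of which leave out a library, and with the block (adjusted p = 0.0569). Among lists not called otherwise, quantile normalization called osteochondrogenic genes lower and NRF2, autophagy, oxidative phosphorylation and ribosomal genes higher, total-count scaling osteochondrogenic genes lower and ribosomal genes higher, no filter cGAS-STING, glycolysis and sex-linked genes lower, and a mean of at least 50 counts NRF2, nerve and ribosomal genes higher. By Fisher's exact test the odds ratio near Sting1 was 0.6859 (p = 0.119) for changes of at least 1 on the log2 scale and 0.7277 (p = 0.109) without protocadherins, and the cause was not tested for these or the other turns. The replicate numbers did not pair the libraries, since residuals of same-numbered libraries correlated at 0.02, −0.06 and 0.05. A replicate block called 9677 genes, 9577 of them the same and in the same direction, and 11 lists. Of 2507 recomputed values of 157 named genes, 2481 kept their direction and side of the threshold. Depth limits genes with few WT counts, where leaving out 1 library moved the fold by over 1.5 times. Ppbp had 6 of 8 WT counts and Lrrn4 13 of 17 in WT 1, Atg9b 11 of 13 in WT 2, and Nos2 6 of 8, Cldn4 3 of 5 and Hoxc10 2 of 2 in WT 3. Col2a1, with more counts, went from −4.84 to −4.01 on the log2 scale without WT 1.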

Other observations

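The tests of Hox position and of the families in this part were chosen after the values were seen, and the test of genes near Sting1 was planned. Some genes of the cornified envelope, the outer shell of keratinocytes, were higher in the libraries labelled KO, without a list fixed beforehand or a test of enrichment. All 8 tested of 21 Lce genes rose, and their summed level went from 1.84 to 57.1 CPM. Of 6 tested of 16 Sprr genes 4 rose and none fell, and their summed level went from 4.39 to 72.2 CPM. Keratin genes rose in 7 of 9 tested cases, from a summed 18.9 to 44.2 CPM. Serpinb genes, a family of protease inhibitors, went both ways, with 12 higher and 5 lower of 18 tested, and their summed level went down, from 2709 to 1920 CPM. The median log2 change of the Lce, Sprr, keratin and Serpinb genes lay above 0 with TMM, quantile, DESeq2 and total-count scaling, for Serpinb genes against the sign of their summed level. The filter lets a gene pass through the 3 libraries labelled KO alone, which favours rises among genes with few WT counts. Single members of these families share reads, and fitted changes of members with few WT counts depend on the prior count.

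Hox genes, which mark the position of a cell along the body axis, went apart by their place in the clusters. Of the 10 tested genes with paralogue numbers 8 to 13, 7 rose and 1 fell in the libraries labelled KO, and of the 17 with numbers 1 to 7, 2 rose and 9 fell. Total-count scaling turned the larger side of the whole list, to 14 higher and 6 lower. Hoxb9 rose 1.45-fold and Hoxc10 went from 2 to 131 counts over 3 libraries each, whereas Hoxb3 fell by 0.68 on the log2 scale and Hoxa2 fell 1.99-fold. A hypothesis is that the cultures may come from different levels of the vessel tree or hold different cells by origin. Across the 27 genes, which are not independent replicates, the log2 change went with the paralogue number (Spearman's rho = 0.6651, permutation p = 0.0002; Pearson's r = 0.603, permutation p = 0.00062). These are 2 statistics of the same relation, and both restate the split that prompted the hypothesis. Over the 19 genes with at least 5 CPM in either group rho was 0.42 (permutation p = 0.072), so the origin of the cells stays open.

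Flanking DNA of another strain, which a knockout made in cells of that strain could carry, would raise the share of called genes near Sting1. The odds ratio of 0.5495 lay below 1 and its 95% interval ended at 0.765, so no such excess was seen in these counts. Without protocadherin genes the odds ratio was 0.7277 with a 95% interval of 0.49 to 1.087. As 64.8% of the genes elsewhere were called, a small excess could be missed.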
